A study of Mus musculus with 4 samples.

How the data were processed

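Total RNA of mouse ovaries was sequenced from strand-specific TruSeq libraries on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name HISAT, Cufflinks and the mouse build mm9, without versions or roles, and the tool that made the estimated counts is not given in the sources used here. Each of the 4 deposited tables covers 1 library and gives, per the file headers, an expected count, an FPKM value and a length for every listed feature, together with its transcripts. The expected counts are the authors' estimates, and between 65.3% and 67.8% of them per library are whole numbers exactly as printed, to at most 2 decimals. The FPKM values are the authors' normalization of those counts to feature length and library total. The deposited length is a weighted mean over transcripts, which need not be whole for features with several transcripts. The smallest FPKM listed in every table is 0.01, so a feature missing from a table was taken as 0 counts there, and missing features are called unlisted. The deposited tables are described as lncRNA tables. Whether each listed feature is an lncRNA was not checked, and RNA outside the tables was not analysed here.

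The library totals behind the FPKM values were recovered by fitting the ratio of count to FPKM on length as a straight line, over features with at least 500 counts and 1000 bases. Between 400 and 608 features per library entered the fit, and 100% of them lay within 2% of the line. The slopes gave totals of 49291013 and 49187682 for the day 3 libraries and 44343534 and 41417035 for the cultured libraries. Wilson 95% intervals of the shares of counts in single libraries were at most ± 0.0201 percentage points. Reads without molecular identifiers are not independent molecules, and intervals and floors cover counting error only.

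Libraries were grouped by the labels as day 3 ovary (2) and ovary taken at day 3 and cultured for 8 days (2). Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.794 and 0.842 at day 3, 1.45 and 1.03 after culture) and the quasi-likelihood F test, two-sided. The design fixed before the data were examined foresaw limma on log2(FPKM + 0.5) for FPKM values and edgeR in its place where the tables held counts or estimated counts, as they did. Features entered with FPKM of at least 0.5 in 2 or more libraries, whatever their group, and were called at an adjusted p below 0.05 (Benjamini-Hochberg). The printed standard error of a log2 fold change is its size divided by the square root of the F statistic. A fold against a group with no counts was computed against a floor of 3 counts per library. Single library measures were compared with exact permutation tests in scipy 1.17.1.

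Features were named by a rule fixed before the data were examined. It took the largest fitted rises and falls among called features with no overlap between the groups' libraries and a mean FPKM of at least 1, with at most 2 identifiers per direction where the tables pair no symbols. No identifier of the tables occurred in the mouse gene tables and annotation at hand (0 matched), none of which is of build mm9. The 29 gene lists fixed beforehand, with 501 distinct symbols, therefore matched 0 features and were not tested, and the named genes and cell type markers among them were not analysed here. Identifier class was tested in their place with camera and fry of limma 3.58.1, a choice made after the identifiers were seen. Abundant features are given by rank and length.

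The tests were checked on simulated counts for the 8557 features with a dispersion of 0.1, near the common dispersion of 0.0991 in the data, and 200 changed features. For this comparison edgeR called 4 of 74 features changed 2-fold, 40 of 62 changed 4-fold and 62 of 64 changed 8-fold, and 4 unchanged features were called. Most 2-fold changes were therefore not detected in this simulation. It held 200 changed features, fewer than the 1229 called in the data, so its cutoff after adjustment was stricter. Detection of 2-fold changes in the data may thus differ from these numbers. The smallest log2 fold change called in the data was 1.12 in size.

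Alternatives were DESeq2 1.42.0 on the counts, limma on log2(FPKM + 0.1), log2(FPKM + 0.5) and log2(FPKM + 1), limma with quantile normalization, with trimmed-mean scaling, without an intensity trend and with a replicate block, edgeR with a replicate block, no filter on low values, a filter at FPKM 1, a 2-fold minimum, and each library left out in turn. Added after the data were seen were scaling by the library totals behind the FPKM values, median-ratio size factors in edgeR, removal of the 10 most abundant features, and keeping a single feature from each set that shares reads. Sets sharing reads were features of the same length whose counts lay within 10% of each other in every library, with a mean of at least 10 counts.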

Results

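RNA was measured in ovaries of 3-day-old mice (2 libraries) and in ovaries taken at the same age and then cultured for 8 days (2 libraries). The labels describe these stages as before and after follicle initiation, the step at which resting primordial follicles, small oocytes enclosed by flat somatic cells, start to grow. Each deposited table lists long non-coding RNA (lncRNA) features with an estimated count, an FPKM value (fragments per kilobase of feature, scaled to the library total) and a mean transcript length. Identifiers took either of 2 forms, NONMMUG, the prefix that the NONCODE database gives to mouse genes, or LXLOC, whose meaning is not given in the sources used here. The tables do not pair the identifiers with gene symbols, and features are described here by identifier, length or rank. The estimated counts summed to 26566784 and 26324839 in the day 3 libraries and to 20939363 and 18215834 in the cultured libraries. A total of 50821 features, 47459 NONMMUG and 3362 LXLOC, were listed in at least 1 library, and 26658 were listed in all 4.

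The first comparison asked which lncRNA features differed in abundance between day 3 ovaries and cultured ovaries. Of 8557 features tested, 502 were higher and 727 were lower after culture (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment, 2 libraries against 2). The median log2 fold change was 2.07 among the features that rose and -2.12 among those that fell, or 2.05 and -2.11 with features listed in only 1 of the groups set at their lower bound against a floor of 3 counts per library. Changes of 4-fold or more, counted with the same bounds, made up 257 of the rises and 396 of the falls. Both cultured libraries lay beyond both day 3 libraries in FPKM for 1227 of the 1229 changed features. These features were chosen by a test on the same libraries, so this is not separate support for them.

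The balance of rises and falls depended on how the libraries were scaled. TMM scaling (trimmed mean of M-values) placed the median log2 fold change of all tested features at 0.08, and 40.8% of the changed features were higher after culture. Scaling by the library totals behind the authors' FPKM values placed that median at 0.45 and gave 415 higher and 269 lower features in edgeR, 60.7% of them higher, while limma on the FPKM values as deposited gave 443 higher and 380 lower. Limma gave 382 higher and 758 lower after trimmed-mean scaling of the same values, 33.5% of them higher, and 429 higher and 655 lower after quantile normalization, 39.6% of them higher. In edgeR, 384 rises and 267 falls were called under both scalings, and no feature was called in opposite directions. The smallest log2 fold change called with TMM scaling was 1.12 in size, larger than the shift of the median between the scalings. Opposite calls could therefore hardly arise, and their absence is not support for the calls. The scalings differed mainly in cultured library 1. Relative to those library totals, and centred on the mean of the libraries, its TMM scale was 0.45 (log2). It was -0.12 for cultured library 2 and -0.20 and -0.13 for the day 3 libraries. The median difference in log2(FPKM + 0.5) from day 3 libraries 1 and 2 was 0.50 and 0.45 for cultured library 1. For cultured library 2 it was 0.05 and -0.01. Without cultured library 1, 387 features were higher and 388 lower, and without day 3 library 1 the numbers were 232 and 354. The labels do not say whether the libraries of a group came from separate animals or pools, and the p-values therefore measure the spread between these libraries, which may be technical. Time since birth and culture differ together between the groups.

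**Figure D1:**
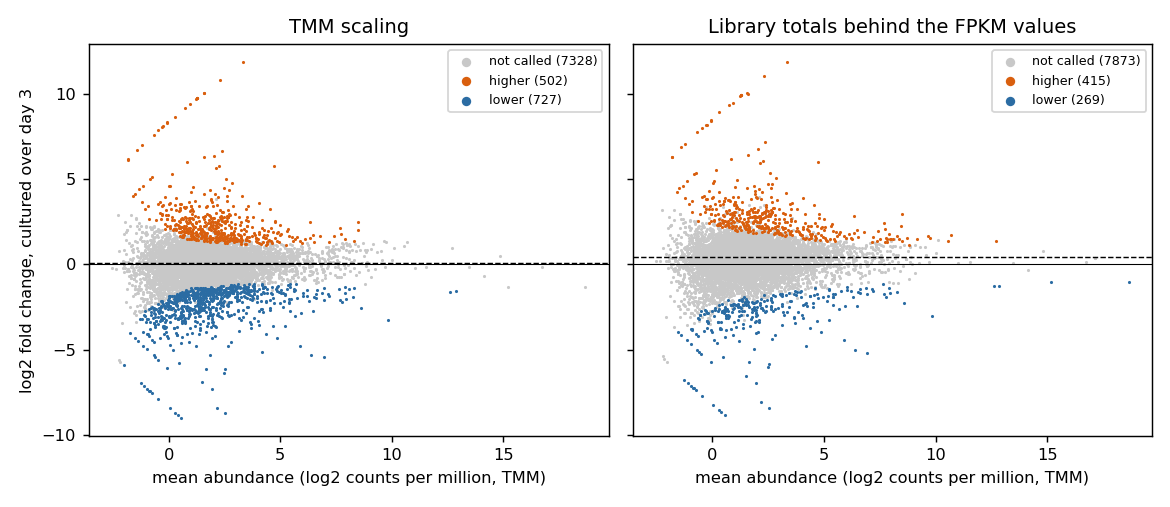
Log2 fold change (cultured over day 3) against mean abundance (log2 CPM, counts scaled to library size by TMM) for the 8557 tested lncRNA features, with TMM scaling on the left and the library totals behind the FPKM values on the right. Orange points were called higher (502 and 415) and blue points lower (727 and 269), and the dashed line marks the median of all tested features (0.08 and 0.45).

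Among changed features with a mean FPKM of at least 1 over the 4 libraries, 247 rose and 369 fell with no overlap between the groups' libraries, and those with the largest fitted changes in each direction were as follows. NONMMUG005850.2, with a single transcript of 3381 bases, was unlisted in both day 3 libraries and reached FPKM 2.09 and 4 in the cultured libraries, from 308 and 551 counts. It was at least 143-fold higher against the floor of 3 counts per library (edgeR, adjusted p = 3.2e-05), and at least 74.2-fold without cultured library 2. NONMMUG066191.1, of 775 bases, was also unlisted at day 3 and had FPKM 1.27 and 6.52 after culture, at least 42.0-fold higher (edgeR, adjusted p = 0.000734). That bound rested mostly on cultured library 2, with 193 counts against 40 in cultured library 1, and was at least 9.74-fold without cultured library 2 and at least 74.3-fold without cultured library 1. LXLOC_047796, of 471 bases, had FPKM 3.07 and 2.19 at day 3 and was unlisted in both cultured libraries, at least 18.9-fold lower after culture (edgeR, adjusted p = 0.000219). NONMMUG008484.2, of 824 bases, had FPKM 3.98 and 9.14 at day 3 and 0 and 0.03 after culture. Its summed counts were 491 at day 3 and 1 after culture, a ratio of 552 (95% exact binomial interval 98.6 to 21851, counting error only; edgeR, adjusted p = 3.2e-05). The ratio was 213 without cultured library 1 and 346 without day 3 library 2, and without cultured library 2 the feature was at least 112-fold lower after culture. Positions and annotation of these features in the genome were not used here.

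A small number of very abundant features held most of the counted reads, and their shares shifted between the groups. Whether these features also hold reads of other RNA, such as ribosomal or mitochondrial transcripts, was not analysed here, and their shares and FPKM are those of the listed features. Features were ranked by their mean count over the 4 libraries, an order that differs within each group and by FPKM. The feature with the most counts, called the most abundant here, was a single transcript of 2555 bases and took 47.8% ± 3.13 (SD, n = 2) of the counts in the day 3 libraries and 27.7% ± 2.57 (SD, n = 2) in the cultured libraries. Its FPKM was 103055 ± 7169 at day 3 and 50714 ± 7211 after culture (SD, n = 2 each), below that of the shorter features ranked 2 to 4 in both groups. A pair of 297-base features with equal counts in every library, uncertain as separate genes because reads may be shared between them, each took 11.5% ± 0.941 at day 3 and 17.4% ± 1.77 after culture (SD, n = 2 each). This pair passed the test under neither scaling. The log2 fold change was 0.07 with TMM scaling (SE 0.601, edgeR adjusted p = 0.955). With the library totals behind the FPKM values it was 0.36 (edgeR adjusted p = 0.282). The features ranked 9 (1545 bases) and 11 (mean length 1190 bases) fell after culture, with log2 fold changes of -1.59 (SE 0.503) and -1.60 (SE 0.492) and edgeR adjusted p-values of 0.0467 and 0.0420. With TMM scaling the most abundant feature had a log2 fold change of -1.35 (SE 0.648, edgeR adjusted p = 0.193) and the feature ranked 5, of 955 bases, one of -1.35 (SE 0.546, adjusted p = 0.121), and neither passed the test. With the library totals behind the FPKM values both fell, with log2 fold changes of -1.02 and -1.01 (edgeR adjusted p = 0.0152 and 0.0256), and the feature ranked 10, with 27 transcripts, rose with one of 1.36 (adjusted p = 0.0212). With TMM scaling the feature ranked 10 did not pass the test (log2 fold change 0.98, SE 0.482, edgeR adjusted p = 0.205). Its share of counts was 0.357% ± 0.0145 at day 3, below that of rank 11 (0.749% ± 0.104), and 1.07% ± 0.355 after culture, above that of rank 9 (0.443% ± 0.0599, SD, n = 2 each).

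For the share of the top 10, features were ranked by count within each library alone. The top 10 held 90.8% ± 0.30 of the counts at day 3 and 85.3% ± 2.24 after culture (SD, n = 2 each). These sets need not hold the same features in both groups. The listed features held 53.7% ± 0.268 of the library totals recovered from FPKM at day 3 and 45.6% ± 2.29 after culture (SD, n = 2 each). For the share of the most abundant feature, of the top 10 and of the listed features, the exact two-sided permutation p was 0.333, the smallest that 2 libraries against 2 allow. Cultured library 1 stood apart in the number of features at FPKM 0.5 or above, with 11211, against 6991 in cultured library 2 and 7025 and 7334 in the day 3 libraries (exact permutation p = 1 between groups).

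**Figure D2:**
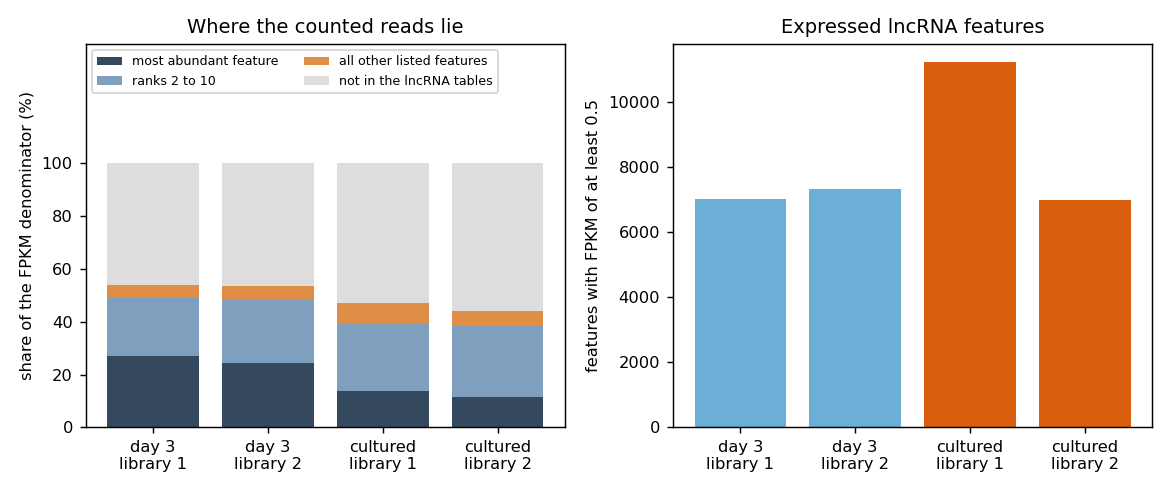
Left, share of each library's FPKM denominator (%) taken by the most abundant feature, by ranks 2 to 10, by all other listed features and by reads outside the lncRNA tables. Ranks on the left are those within each library. Right, number of features with FPKM of at least 0.5 per library, with day 3 in light blue and cultured in orange, where cultured library 1 reaches 11211 and the others lie between 6991 and 7334.

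The 2 classes of identifier were then compared, and with TMM scaling falls made up 24.7% of LXLOC features and 5.63% of NONMMUG features. Of 1290 LXLOC features tested, 65 rose, 318 fell and 907 did not pass the test, with a median log2 fold change of -0.54. Of 7267 NONMMUG features, 437 rose, 409 fell and 6421 did not pass, with a median of 0.15. Adjusted over the list alone, 86 LXLOC features rose and 383 fell, and 377 NONMMUG features rose and 362 fell. On the scale of the authors' FPKM totals the medians were -0.22 for LXLOC and 0.51 for NONMMUG, with 60 LXLOC features higher and 135 lower and 355 NONMMUG features higher and 134 lower. Placing features listed in only 1 of the groups at their bounds left both medians at -0.54 and 0.15.

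LXLOC features ranked below NONMMUG features by camera with a preset correlation of 0.01 between features (adjusted p = 2.16e-09, 2 classes, chosen after the identifiers were seen). The call was lost with the correlation estimated from LXLOC features (adjusted p = 0.194 with an estimated correlation). The 2 classes make up all tested features, so the NONMMUG test is the same contrast with the correlation estimated from the other class (adjusted p = 0.0251 with an estimated correlation) and is not a separate result. Limma's rotation test fry gave an adjusted p = 0.125 for features moving one way on balance and an adjusted p = 0.00768 for change in either direction, the same adjusted values in both classes. The median log2 difference of LXLOC features minus that of NONMMUG features was -0.66 for the cultured minus the day 3 libraries. Between single libraries of a group it was 0.45 for cultured library 2 minus 1, and 0.04 for day 3 library 2 minus 1. The other splits of 2 libraries against 2 mix the groups and are made up of these same within-group differences, averaged. They gave 0.23 for libraries 2 minus libraries 1, and -0.18 for day 3 library 2 and cultured library 1 minus the rest. Without cultured library 1, 171 LXLOC features fell and 63 rose, and without day 3 library 1 the numbers were 180 and 41.

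**Figure D3:**
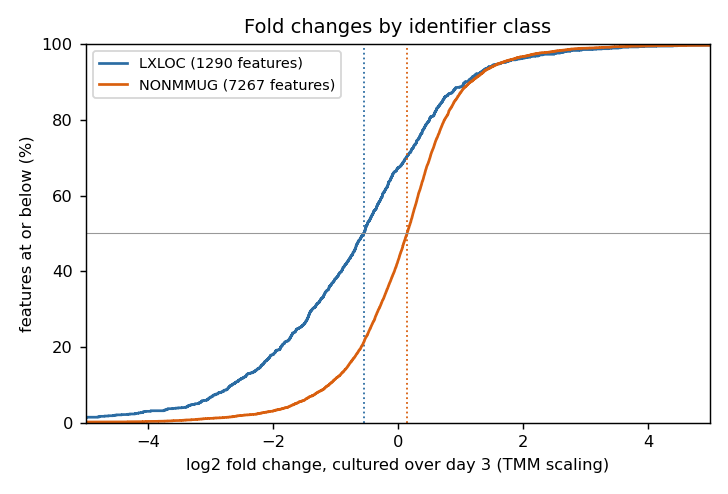
Cumulative share of features (%) at or below each log2 fold change (cultured over day 3, TMM scaling), for 1290 LXLOC features in blue and 7267 NONMMUG features in orange. Dotted lines mark the medians, -0.54 and 0.15.

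The libraries of a group were closer to each other than to those of the other group. Across the 8557 tested features, which are not independent replicates, Pearson's r of log2(FPKM + 0.5) was 0.952 between the day 3 libraries (Spearman's rho 0.828) and 0.925 between the cultured libraries (rho 0.777). Between groups, r ran from 0.797 to 0.872. The SD of the difference between libraries of a group was 0.42 at day 3 and 0.54 after culture on the log2 scale. Counts differed between the libraries of a group by more than sampling noise, with a chi-square per degree of freedom of 39.0 at day 3 and 64.4 after culture. No pair was therefore treated as 1 library deposited more than once, which does not show that the libraries came from separate animals.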

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

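Alternative scaling by the FPKM totals, median-ratio factors, removal of abundant features and removal of shared reads were chosen after the data were seen. No alternative called a feature in the direction opposite to TMM-scaled edgeR, and NONMMUG005850.2, NONMMUG066191.1, LXLOC_047796 and NONMMUG008484.2 passed the test with the same direction in all of the 19 alternatives run on them. The alternatives reused the same libraries, and the smallest log2 fold change called in TMM-scaled edgeR was 1.12 in size. Opposite calls were therefore unlikely beforehand, and their absence is not separate support. Against 1229 changed features (502 higher, 727 lower), the number was 2540 (1133 and 1407) with no filter and 50821 features tested, and 744 (309 and 435) at FPKM 1 with 4166 tested. It was 684 with the FPKM totals (269 lower). Limma gave 380 lower features with a pseudocount of 0.5, 741 changed with 338 lower at 0.1, 747 with 356 lower at 1, and 494 (275 and 219) without the intensity trend. The fall in lower features followed the scaling, since edgeR with only the scaling changed showed it and limma gave 758 lower features after trimmed-mean scaling and 655 after quantile normalization. The cause was not tested for the pseudocounts and the intensity trend. Leaving out each library in turn, with the lone library assumed to vary like the pair, gave 586 to 1260 changed, 232 to 412 higher and 354 to 848 lower features. DESeq2 called 1084, of which 1032 were among the 1229, and a 2-fold minimum removed none. The replicate numbers are not said to pair libraries, and same-numbered libraries did not deviate together (r = -0.139 across features). A replicate block gave 1204 changed features in edgeR (497 higher, 707 lower) and 1019 in limma, with 446 lower. The LXLOC median minus the NONMMUG median, -0.69, stayed negative in 19 alternatives, from -0.33 to -0.98, and the number of LXLOC features that fell moved by over 1.5 times in 10 of them. The gene list alternatives were not run, since no symbol matched.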

Other observations

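The tests on LXLOC features seen only after culture, on consecutive identifiers and on transcript length, and the length classes, were chosen after the results were seen, as were the bound on an even background and the counts at other minimums. Some lncRNA features were listed in both libraries of a group, with at least 20 counts in each, and in neither library of the other group. After culture 27 features met this (4 LXLOC and 23 NONMMUG), and at day 3 there were 15 (8 LXLOC and 7 NONMMUG). The 4 other ways of setting a pair of libraries against the rest gave 5, 1, 6 and 17 features. With a minimum of 10 counts the numbers were 57 after culture and 51 at day 3, and with 50 counts 11 and 1. A set of 5 features of 991 bases, which rose together and whose counts lay within 10% of each other, made up 5 of the 27 and is uncertain as 5 separate genes.

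The median log2 fold change was higher in each longer class of feature length, a trend that was not tested. Of 726 features under 500 bases, 23 rose and 81 fell, with a median of -0.26, and of 1950 features from 500 to under 1000 bases, 78 rose and 217 fell, with a median of -0.04. The 2776 features from 1000 to under 2000 bases had a median of 0.09, with 154 rises and 232 falls. Of 2592 features from 2000 to under 4000 bases, 205 rose and 155 fell, with a median of 0.19, and of 513 features of 4000 bases or more, 42 rose and 42 fell, with a median of 0.23. On the scale of the FPKM totals the medians were 0.07, 0.31, 0.46, 0.56 and 0.59 in the same order, so those of the 2 shortest classes changed sign. The rises and falls on that scale were 23 and 30, 64 and 78, 133 and 87, 159 and 55, and 36 and 19. Mean transcript length of 1043 features with several transcripts passed the limma test in 0 cases (smallest adjusted p = 0.0898). Of these features, 116 had an unadjusted limma p under 0.05, 83 longer and 33 shorter after culture. The SD of the length difference across features was 0.156 between the groups, against 0.115 and 0.120 in the splits that mix them. Whether mean transcript length changed with culture could therefore not be decided.

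Cultured library 1 had 11211 features at FPKM 0.5 or above, and 3484 features reached that level in it alone. Greater depth was argued against, since the total behind its FPKM values (44343534) was below those of both day 3 libraries (49291013 and 49187682). Thinning to the smallest library total (41417035) left 11118, 1.52 times the highest other library (7334). That thinning removed few reads from values already scaled to depth, so it could hardly have changed the number. A smaller share taken by abundant features could account for part of the gap, but FPKM recomputed without the top 10 still gave 1.36 times the highest other library (10543 against 7751). An even background of 0.225 FPKM was argued against, since 40.9% of 31954 long features listed elsewhere reached that value in this library. That value was set from the median excess of 0.45 FPKM in the 3484 features, which were chosen for being high in this library. The largest background that 95% of the long features allow is 0, but features may also go uncounted under a weak background. A weaker or an uneven background was not tested. A different tissue makeup or RNA quality of this culture stays open, and no biological explanation was tested, since the labels give none within a group.

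The lower fold changes of LXLOC features were set against technical explanations. Length and abundance were argued against, since matched NONMMUG features left a difference of medians of -0.66 (SD 0.0300 over 200 draws), close to the unmatched -0.69. Assembly of LXLOC features from day 3 reads alone was argued against, since 4 LXLOC features were listed only after culture. Their presence bears on that extreme form alone. They were 0.119% of the 3362 LXLOC features, against 0.0485% of the 47459 NONMMUG features. Features listed only at day 3 were 0.238% of LXLOC against 0.0147% of NONMMUG features. The filter passed 1290 LXLOC and 7267 NONMMUG features, a larger part of the LXLOC class. These shares of all listed features therefore do not compare the classes at like abundance, and no conclusion is drawn from them. Assembly that leaned towards day 3 reads without resting on them alone stays open, and a response of this class to culture may be present. The class difference for cultured minus day 3 libraries (-0.66) was larger in size than in the splits that mix the groups (0.23 and -0.18). Those splits average the differences between libraries of the same group and add no separate reference. With 2 libraries per group the class difference was not firmly separable from differences between libraries. The single cultured libraries differed by 0.45.

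Fold changes of NONMMUG features with consecutive numbers were correlated across 1784 pairs (Pearson's r = 0.43, Spearman's rho 0.46), above the highest of 1000 permutations (0.0754) and above pairs of features more than 20 numbers apart (r = 0.07). Of 84 pairs with both members changed, 82 moved the same way. Consecutive features may respond together to culture. However, the difference between the cultured libraries was itself correlated across these pairs (r = 0.33, and 0.20 at day 3). The correlation of fold changes exceeded that of the cultured libraries by 0.0958 (SE 0.0285). This gap was larger than its SE but fell short of the bound of 0.1 set for it. The use of that bound with an error was settled after the value was seen. Since libraries of a group also differed in a correlated way, a shared response and a shared technical source, such as overlapping features, cannot be told apart. Whether consecutive numbers lie side by side in the genome was not checked here.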
